A study of Homo sapiens with 16 samples.

How the data were processed

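Single-cell RNA sequencing of dissociated tumour biopsies was deposited as 14 libraries from 10 patients, 10 from biopsies before and 4 from biopsies after treatment with plinabulin, radiation and checkpoint blockade. A further 2 samples of pooled blood cells had no files and were put in no group. Per the labels' protocols, biopsies were dissociated at a warm temperature, strained, cleared of red cells where the pellet was bloody and stored frozen before 10x Genomics sequencing. The authors deposited raw UMI count matrices made with Cell Ranger 6.1.2, per the file headers, with no normalization, and cell barcodes had been called before deposition. The submitters' processing notes name hg38 and GRCm38, and no mouse gene was in the files, which list 36601 human genes. The annotation release is not stated. Gene positions were taken by gene ID from GENCODE 29 on GRCh38, which held 34616 of the genes (94.6%).

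The tests, gene lists, cell type markers, patients compared and the rule for the genes named were set before the data were examined. Cells with at least 500 UMIs, 250 genes and at most 20% mitochondrial UMIs were kept. In each library the cells with the highest Scrublet scores (scanpy 1.11.5) were removed at a rate of 0.8% per 1000 barcodes, 2083 in all. The count of cells used was 43385, with 6263254 to 73698627 UMIs per library. A total of 646 immunoglobulin and T cell receptor genes and 103 Y-linked genes and XIST were left out of every test, and they took 0.001% to 29.7% of UMIs per library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were joined to 20 neighbours and clustered with leidenalg 0.10.2 at resolution 1, with no batch correction. This gave 43 clusters, of which 10 were left unnamed. Together with 253 cells left out of named clusters, 15.8% of the cells had no class.

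A cluster was named when at least 3 markers and at least 50% of the markers of a type were raised 2-fold over other cells. A cluster that failed this was named epithelial when at least 6 epithelial markers were detected in 10% of cells. Any cluster was then left unnamed when its leading genes held more markers of another class than of its own. So was a shallow cluster with no marker of its own class among those genes. These naming rules, and leaving out 253 cells in subclusters with markers of another class, were set after the clusters had been seen. Subset names such as CD8 T-like describe marker genes of clusters and not sorted cells. An unnamed cluster of 1513 cells led by keratins, with 7 epithelial markers raised, was counted as epithelial in 1 alternative. It had met the marker rule and was left unnamed because of the markers among its leading genes. Leading genes of epithelial, unnamed or single-patient clusters are not printed.

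For each library and class the UMIs of its cells were summed, so the library and not the cell was the replicate. A class was tested where at least 3 patients had at least 20 cells in both biopsies, which held for T and NK, myeloid and epithelial cells (patients A, B and D) and for all cells summed. Changed genes were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, R 4.3.3) in the 8 libraries of patients A to D, after against before, with no patient term, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. SE is the log2 change divided by the square root of the test's F value. The alternative with the patient as a block is printed where it changed a call, since the biopsies pair by patient. In that check the deviations of the 2 biopsies of a patient from their group means correlated at 0.807 to 0.918 for summed cells, 0.110 to 0.438 for T and NK cells and 0.384 to 0.588 for myeloid cells, across genes.

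Gene lists with at least 5 tested genes were compared with all other genes by limma 3.58.1's camera, two-sided, with a preset correlation of 0.01 and a prior count of 2, adjusted over 77 tests in 4 classes. The lists were tubulin genes, GEF-H1, RhoA and AP-1, dendritic cell maturation, pro-inflammatory macrophage, scavenger and tissue-resident macrophage, type I interferon, interferon gamma response and antigen presentation, cytotoxicity, inhibitory receptors, naive and memory T cell, regulatory T cell, cell cycle, p53 targets, NF-kB targets, hypoxia, unfolded protein response, heat shock, collagen, vascular, mitochondrial and platelet genes. A haemoglobin list had too few tested genes. Camera worked on log2 CPM (UMI counts scaled to a common library total), while counts of higher members and median changes came from the edgeR fit. The heat shock list is of heat shock and dissociation genes together. It shares FOS, FOSB, JUN, EGR1 and ATF3 with the GEF-H1, RhoA and AP-1 list. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance 1 way and not whether they differ from other genes, were run beside it.

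Shares of cells were compared as log2 odds with 0.5 cells added, by an exact two-sided permutation test over 70 allocations of the 8 libraries, adjusted over the classes or subsets. The sign-flip test within 4 patients can reach 0.125 at the lowest. Correlations used 100000 permutations, two-sided. Shares are for the cells recovered, and no interval for single libraries is given. Counting error within a pair was not tested, so a count of patients with 1 direction can include differences within it.

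Genes were named by a fixed rule that took, per class, up to 10 higher and 10 lower genes by smallest p with 1 direction in all patients, filled from the fit with the patient block and then by unadjusted p, along with 2 members of each list with the largest change and genes followed throughout. MMP9 within myeloid cells and C1QC and C1QB levels in myeloid cells were chosen after their values were seen. Among rule-named genes the text gives a part, and genes chosen by p in epithelial cells are mostly left out to protect single patients.

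The tests were checked on simulated data with 200 changed genes drawn at the real means and library sizes. With the patient block, edgeR on these data called 92%, 98%, 100% and 76% of 4-fold changes in summed, T and NK, myeloid and epithelial cells, with 25, 9, 20 and 42 false calls. A list changed 2-fold was called by camera with the preset correlation in all 4 classes, and with an estimated correlation in all but epithelial cells (adjusted p = 0.194).

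Alternatives were DESeq2 1.42.0 size factors, library totals without TMM, no filter on low counts, the patient block, all 14 libraries, no doublet removal, a strict cell filter (1000 UMIs, 500 genes, 10% mitochondrial), Leiden resolution 0.5 and 2, shares among immune cells and leaving out each library. Leaving out 1 library kept that patient's other biopsy in, with no patient term. Such values therefore mix differences between patients with the change after treatment. Dropping patient C, counting the keratin-led cluster as epithelial and taking the FOXP3 cluster at resolution 2 as regulatory T cells were chosen after seeing the data. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.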

Results

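Gene expression was measured in single cells from dissociated tumour biopsies of 10 people with cancer who received plinabulin, radiation and immune checkpoint blockade. Plinabulin is a small molecule that binds tubulin, and checkpoint blockade uses antibodies against inhibitory receptors such as those on T cells. There were 10 libraries from biopsies before treatment and 4 from biopsies after it, each biopsy giving 1 library. The 4 patients with both biopsies are called A to D here, and the 6 with a biopsy before treatment alone are called E to J. Whether a patient responded was not among the labels used.

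The deposited count matrices held 62711 cell barcodes, with 1245 to 8535 per library. In patients A, B, C and D the total count was 22748222, 93778223, 23065887 and 52400815 unique molecular identifiers (UMIs) before treatment. After treatment it was 50957830, 52908763, 6875960 and 67757955 UMIs. Patients E to J had 62314459, 27445841, 86514082, 23991899, 47349461 and 37564548 UMIs. A total of 43385 cells were used, 1111 to 7021 per library. The median depth per used cell averaged 11660 ± 7005 UMIs before and 6917 ± 6198 UMIs after treatment in patients A to D (SD, n = 4), and it was lowest, 1351.5 UMIs, in patient C after treatment. Barcodes with more than 20% mitochondrial UMIs were left out, which removed 46.1% of barcodes before and 61.6% after treatment in patient D, against 8.91% to 33.9% in the other 6 of these 8 libraries.

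The first comparison asked which cell types filled the biopsies before and after treatment. Myeloid cells, which take in macrophages, monocytes and dendritic cells, made up 6.04% ± 3.79 of cells before and 14.4% ± 7.08 after treatment (SD, n = 4), a 2.63-fold difference in odds. Their share was higher after treatment in 4 of 4 patients. Epithelial cells, the class that would hold carcinoma cells, made up 43.1% ± 21.0 before and 32.8% ± 25.9 after (SD, n = 4), lower in 4 of 4 patients. In patient C this rested on an unnamed cluster led by keratins, which held 584 of that patient's cells before and 850 after treatment. Counted as epithelial, it raised the share in patient C from 13.9% to 66.4% before and from 0.353% to 75.4% after, and the means to 56.9% ± 9.43 and 51.7% ± 21.3, lower in 3 of 4 patients. T and natural killer (NK) cells made up 21.3% ± 7.35 before and 18.2% ± 13.3 after treatment, higher in 2 of 4 patients. No class passed the exact two-sided permutation test over the 70 allocations of the 8 libraries, whose smallest possible p is 0.0286. For myeloid cells the exact p was 0.114 (adjusted p = 0.821 over 10 classes), and for epithelial cells it was 0.514 (adjusted p = 0.821). The exact sign-flip test within patients gave 0.125 for both classes, the smallest p that 4 patients allow.

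Smaller classes showed no common direction over the 4 patients. B cells held 1.53% ± 2.59 before and 0.401% ± 0.739 after, and plasma cells 2.57% ± 3.39 and 3.84% ± 5.34. Fibroblasts held 3.32% ± 4.92 and 4.15% ± 7.47, where the mean share was higher after treatment and the mean log2 odds were lower by 2.03, with a share of 15.3% in patient A after treatment and at most 1.29% in the others. Endothelial cells held 0.264% ± 0.256 and 1.10% ± 1.79, mast cells 1.14% ± 1.33 and 1.36% ± 0.920, pericytes 1.04% ± 0.979 and 1.12% ± 1.69, and plasmacytoid dendritic cells 0.058% ± 0.116 and 0.0947% ± 0.111 (SD, n = 4 throughout). Leaving out 1 library moved the log2 odds difference from -0.93 (without patient C before) to -3.39 (without patient B after) for B cells, from -0.62 (without patient D after) to -3.88 (without patient A after) for fibroblasts and from -0.40 (without patient C after) to -2.53 (without patient A after) for pericytes. For plasmacytoid dendritic cells it ran from 0.16 (without patient A after) to 1.28 (without patient B before). It turned sign for plasma cells, from -2.03 (without patient B after) to 1.06 (without patient D after). It also did for endothelial cells, from -0.34 (without patient A after) to 1.82 (without patient C after), and for mast cells, from -0.64 (without patient C before) to 1.48 (without patient C after). The lowest adjusted p among all classes was 0.821 in the exact test. Cells left without a class made up 19.6% ± 23.9 before and 22.6% ± 36.7 after treatment. Among patients A to D most were from patient C (54.1% and 77.4% of that patient's cells). Of these patients, shares in patient C therefore rest on the fewest named cells. Leaving out the library of patient C after treatment turned the mean log2 odds of T and NK cells from -0.70 to 0.13 and of epithelial cells from -1.76 to 0.13. In the 6 patients sampled before treatment alone, the median share was 12.6% for myeloid cells (1.35% to 24.8%), 35.1% for T and NK cells (1.93% to 48.2%) and 0.784% for epithelial cells (0.129% to 42.7%).

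**Figure D1:**
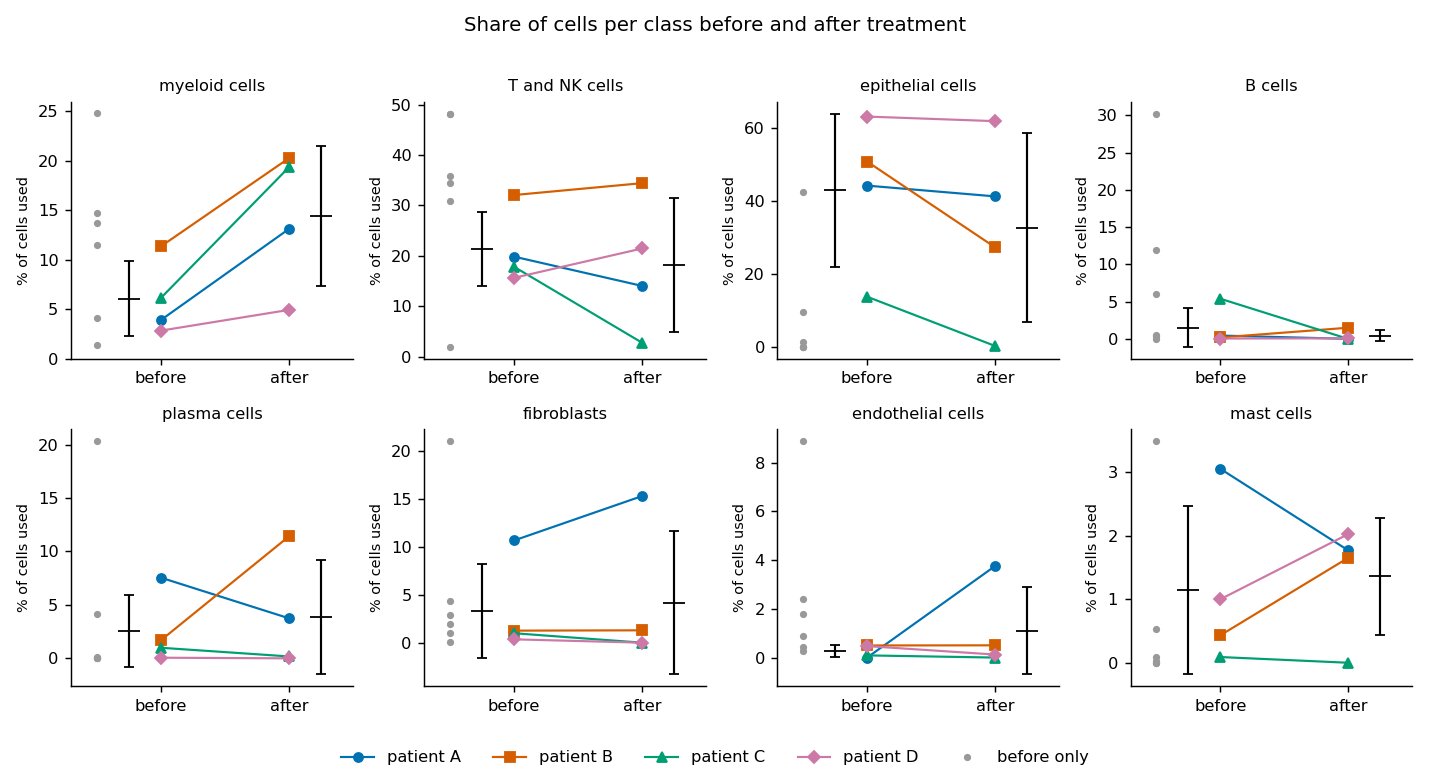
Share of each cell class in percent of the cells used, on the vertical axis, before and after treatment, with points joined for patients A to D and separate points for patients with a biopsy before treatment alone. The myeloid share was higher after treatment in each of the 4 joined patients, while the epithelial share was lower in each, where patient C's unnamed keratin-led cluster was not counted as epithelial.

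Within the T and NK cells, clusters named by their markers were compared. Regulatory T-like cells, a cluster led by CTLA4 and TNFRSF4, made up 12.1% ± 7.78 before and 15.6% ± 12.5 after (SD, n = 4), higher in 4 of 4 patients. This cluster also held other T cells, since at a finer resolution 413 of its 546 cells in patients A to D, and 165 of 1719 in patients E to J, fell in a cluster led by FOXP3 and IL2RA. That finer cluster held 8.63% ± 6.04 of T and NK cells before and 12.1% ± 10.3 after, higher in 3 of 4 patients. CD8 T-like cells, the killer lineage, held 58.4% ± 15.2 and 49.0% ± 15.5 and were higher in 1 of 4 patients. CD4 T-like cells with the memory and naive markers IL7R and CCR7 held 14.7% ± 7.09 and 25.2% ± 20.6, higher in 3 of 4. Their mean log2 odds difference of 0.73 was 0.03 without patient C after, 0.14 without patient B before, 0.45 without patient A after and 1.53 without patient B after. That of CD8 T-like cells, -0.59, was -0.12 without patient C after, -0.35 without patient A before, -0.36 without patient B before and -0.9994 without patient D before. NK-like cells held 12.6% ± 18.2 and 8.48% ± 9.99 and cycling cells 2.24% ± 1.49 and 1.74% ± 1.59, each higher in 2 of 4 patients. None of these subsets passed the exact permutation test, where the unadjusted p lay between 0.486 (CD8 T-like) and 0.943 (cycling) and every adjusted p was 0.943. The exact sign-flip p was 0.125 for regulatory T-like cells, whose mean log2 odds difference of 0.32 turned to -0.22 without the library of patient D before treatment and -0.26 without that of patient B after it. Patient C contributed 31 T and NK cells after treatment, of which 25.8% were CD8 T-like, against at least 54.9% in the other 3 patients. For NK-like cells the mean difference of -0.32 turned to 0.73 without patient D before and 0.33 without patient A after treatment, and for cycling cells 0.05 turned to -0.54 without patient A before and -0.28 without patient D after.

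Within the myeloid cells, SPP1 and C1Q macrophage-like cells made up 19.9% ± 6.92 before and 47.3% ± 39.4 after treatment (SD, n = 4). SPP1 encodes osteopontin, a secreted matrix protein that marks a class of tumour macrophages, and C1Q is a complement component that tissue macrophages make. Their share was higher in patients A (25.5% to 67.1% of myeloid cells) and C (19.1% to 92.7%) and lower in patients B and D. The cells gained need not be of 1 kind. At resolution 2 a myeloid cluster of 1322 cells was led by C1Q genes without SPP1. SPP1 was among the leading genes of a cluster of 201 cells, 84.1% from 1 library. Overlap with these clusters was not counted. MMP9 in SPP1 and C1Q macrophage-like cells after treatment had 27.9 CPM in patient A and 5910 in patient C. Dendritic-like cells, the antigen-presenting subset, held 14.3% ± 11.6 before and 8.13% ± 12.2 after, lower in 4 of 4 patients. In patient B this rested on 3 of 342 cells before and 2 of 282 after, and patient D after treatment had 26.1%. The log2 odds difference of -2.01 was -0.84 without patient C after, -1.34 without patient D before, -3.12 without patient B before and -3.27 without patient D after. That of SPP1 and C1Q macrophage-like cells, 1.88, was 0.61 without patient C after and 2.95 without patient D after. FCN1 monocyte-like cells, a blood-derived type, held 28.0% ± 20.3 and 12.02% ± 13.6 (higher in 1 of 4), and C1Q and CCL3 macrophage-like cells 37.9% ± 24.7 and 32.6% ± 27.1 (higher in 2 of 4). The exact permutation p was 0.229 for FCN1 monocyte-like, 0.286 for dendritic-like, 0.371 for SPP1 and C1Q macrophage-like and 0.714 for C1Q and CCL3 macrophage-like cells, with adjusted p of 0.495 for the first 3. Cells of the SPP1 and C1Q cluster were shallow, at 0.414 of their library's median UMIs, and patients A and C, in whom the cluster grew, had the 2 lowest depths after treatment (2230 and 1351.5 UMIs per cell). The difference for C1Q and CCL3 macrophage-like cells, -0.57 in log2 odds, turned to 0.08 without patient B before and 0.42 without patient C after treatment.

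**Figure D2:**
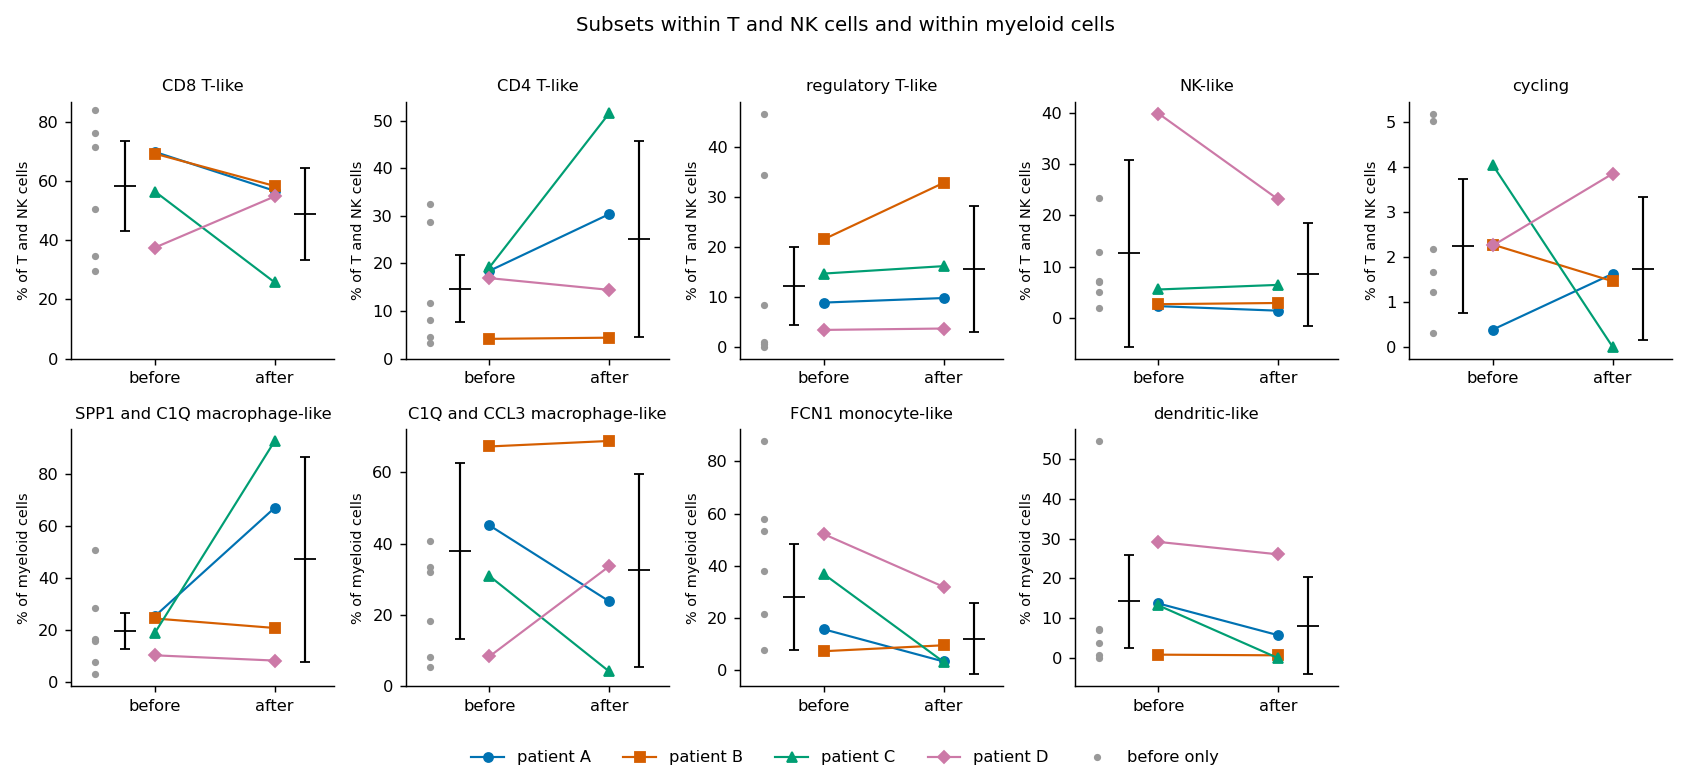
Share of each subset in percent of the T and NK cells or of the myeloid cells, on the vertical axis, before and after treatment, with lines joining the biopsies of patients A to D. The cluster called regulatory T-like, which also held other T cells, had a higher share and dendritic-like cells a lower share after treatment in each of the 4 patients.

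The next comparison asked how expression inside T and NK cells differed after treatment, with UMIs summed per library. The mix of clusters differed as well, as 1 CD8 T-like cluster held 0.38% of the T and NK cells of patient D before and 25.6% after, and CD4 T-like cells 19.2% and 51.6% in patient C. These sums therefore mix a change inside cells with a change in subsets, the cytotoxicity and naive T cell genes included. The genes named first were higher in 4 of 4 patients. NR4A3, a nuclear receptor that T cell receptor signals induce, had 70.5 ± 25.0 CPM (UMI counts scaled to a common library total) before and 134 ± 20.7 after (SD, n = 4), a log2 change of 0.90 ± 0.27 (SE). PHLDA2, a small membrane-binding protein, went from 16.2 ± 5.56 to 44.2 ± 18.3 CPM, a log2 change of 1.48 ± 0.35. TNFAIP3, which restrains NF-kB signalling, had 704 ± 111 and 1196 ± 246 CPM (log2 change 0.77 ± 0.24), and GADD45A, a stress gene, 109 ± 21.4 and 203 ± 81.2 CPM (0.79 ± 0.27). TNFAIP3 and GADD45A passed neither without nor with the patient as a block in edgeR (adjusted p = 0.129 and 0.148 with it). Lower in 4 of 4 patients were GZMB, the killer protease granzyme B, at 620 ± 41.2 and 406 ± 193 CPM (log2 change -0.61 ± 0.35, and -0.31 without patient A after treatment), the activating receptor SLAMF7 (-0.63 ± 0.23) and the G protein regulator RGS16 (-0.66 ± 0.24).

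By edgeR's quasi-likelihood test without a patient term, 0 of 9295 genes passed an adjusted p of 0.05, with 110 at an unadjusted p under 0.05 (64 higher, 46 lower). DESeq2 gave 0 genes and 51 unadjusted. Both unadjusted counts are under what chance alone would give at this p, so they are no sign of a change. With the patient as a block in edgeR, 4 genes passed, and all 4 rose in 4 of 4 patients. They were NR4A3 (log2 change 1.02 ± 0.19, adjusted p = 0.0314), PHLDA2 (1.37 ± 0.27, adjusted p = 0.0496), AC016831.7 (1.62 ± 0.27, adjusted p = 0.0153) and AC016831.5 (0.98 ± 0.19, adjusted p = 0.0388). AC016831.7 and AC016831.5 are long noncoding RNAs of 1 locus, the second lying inside the first on the same strand and the first overlapping LINC-PINT, so their counts are uncertain. AC016831.7 had 13.1 ± 7.68 CPM before and 35.7 ± 11.3 after, and AC016831.5 54.8 ± 19.2 and 102 ± 21.2. Without patient C, whose library after treatment held 31 T and NK cells, 0 genes passed with the block in edgeR (658 at an unadjusted p under 0.05). The log2 changes stayed as large there, at 1.09 ± 0.18 for NR4A3, 1.34 ± 0.29 for PHLDA2, 1.67 ± 0.27 for AC016831.7 and 1.04 ± 0.17 for AC016831.5, with adjusted p of 0.0776, 0.273, 0.0776 and 0.0776 from fewer samples. With no filter on low counts 6 of 22011 genes passed in edgeR without the block, 5 higher and 1 lower, PHLDA2 among them (adjusted p = 0.021). On changes simulated without pairing by patient in T and NK cells, edgeR without the block called 24% of the genes changed 2-fold. It called 96% of those changed 4-fold.

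On GRCh38, NR4A3 (ENSG00000119508) lies on chromosome 9 at 99821855 to 99866891 and PHLDA2 (ENSG00000181649) on chromosome 11 at 2928273 to 2929455. AC016831.7 (ENSG00000285106) spans 130791264 to 131110161 of chromosome 7 and AC016831.5 (ENSG00000271204) 130930209 to 130932206. TNFAIP3 (ENSG00000118503) lies on chromosome 6 at 137867188 to 137883312, GZMB (ENSG00000100453) on chromosome 14 at 24630954 to 24634267 and CTLA4 (ENSG00000163599) on chromosome 2 at 203867771 to 203873965. Further genes higher in these cells were ATF3 (0.96 ± 0.30, 3 of 4 patients), a stress transcription factor, and, in 4 of 4 patients, the survival protein MCL1 (0.63 ± 0.22), MARCKSL1 (0.84 ± 0.28) and the chaperone partner DNAJB9 (0.44 ± 0.21). TNFAIP3 and GZMB each overlap an annotated gene on the other strand, and the labels do not state whether strand was used in counting.

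Among gene lists in T and NK cells, naive and memory T cell genes were higher as a set, with 10 of 12 members higher and a median log2 change of 0.26 (limma's camera, adjusted p = 0.0031, with higher list means in 2 of 4 patients; adjusted p = 0.578 with an estimated correlation). BACH2, which keeps T cells quiescent, had a log2 change of 0.92 ± 0.43 and MAL, a marker of resting T cells, 0.51 ± 0.33 (0.30 without patient B before and 0.79 without patient C before). NF-kB targets were higher in 12 of 14 members (median 0.32, adjusted p = 0.0035, 2 of 4 patients; adjusted p = 0.448 with an estimated correlation). Type I interferon genes were higher in 21 of 25 (median 0.29, adjusted p = 0.0171, 2 of 4 patients; adjusted p = 0.664 with an estimated correlation), with IFIT3, an antiviral gene, at 1.08 ± 0.61 and at -0.34 without patient A after treatment. Dendritic cell maturation genes measured in these cells were higher in 6 of 6 (median 0.46, adjusted p = 0.0228, 3 of 4 patients; adjusted p = 0.546 with an estimated correlation). Mitochondrial transcripts were higher in 9 of 12 (median 0.11, adjusted p = 0.0322, 3 of 4 patients; adjusted p = 0.601 with an estimated correlation). Cytotoxicity genes, the killing machinery of T and NK cells, were lower in 15 of 16 members (median -0.36), and the list mean was lower in 4 of 4 patients. That list gave an adjusted p of 0.062 with camera, 0.636 with an estimated correlation and 0.010 with the patient as a block (adjusted p = 0.74 with the block and an estimated correlation). In the list PRF1, the pore protein perforin, had a log2 change of -0.66 ± 0.40 (higher in 1 of 4 patients; -0.33 without patient A after, -0.39 without patient D before and -0.99 without patient D after) and CX3CR1, a homing receptor of killer cells, -1.13 ± 0.92 (2 of 4), which was 0.60 without patient D before treatment. GEF-H1, RhoA and AP-1 genes, the pathway that tubulin binders can release, were higher in 9 of 15 (median 0.28, adjusted p = 0.062, and 0.045 with the block; adjusted p = 0.618 with an estimated correlation). FOSB, an AP-1 subunit that is also in the heat shock and dissociation list, had a log2 change of 0.77 ± 0.41 in 4 of 4 patients.

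Splits of the same 8 libraries into other groups of 4 gave up to 9 lists past the threshold in these cells, against 5 here. Each of these 5 lists lost its call when some 1 library was left out. The largest adjusted p of limma's camera was 0.174 for naive and memory genes (without patient B before), 0.188 for NF-kB targets (without patient D after), 0.688 for type I interferon (without patient A after), 0.558 for dendritic cell maturation and 0.396 for mitochondrial transcripts (both without patient D before). Inhibitory receptors of T cells were higher in 6 of 15 (median -0.08 with a higher test direction; adjusted p = 0.257). The test direction is that of limma's camera, which works on log2 CPM and sets a list against the other genes. Counts of higher members and medians come from the edgeR fit. The test direction can differ from the sign of the median for either reason. Among them CTLA4, a checkpoint receptor, had 96.7 ± 61.4 CPM before and 157 ± 79.9 after, a log2 change of 0.55 ± 0.50 in 4 of 4 patients. CTLA4 was 0.19 without patient D before, 0.32 without patient C after and 0.88 without patient B before. PDCD1 (PD-1) had 0.14 ± 0.42 in 2 of 4, and LAG3, another checkpoint, -0.36 ± 0.54, which was 0.09 ± 0.30 with the block. PDCD1 was -0.28 without patient B after and -0.17 without patient D before treatment, and LAG3 0.15 without patient B before. IFNG, the effector cytokine, had a log2 change of -0.08 ± 0.30 (0.16 without patient B after, 0.04 without patient C before). FOXP3, the regulator of suppressor T cells, had -0.42 ± 0.64 (0.08 without patient D after). MKI67 had 0.18 ± 0.54 (-0.17 without patient A before, -0.40 without patient D after) and CDKN1A, a p53 target, 0.37 ± 0.26 (0.18 without patient D before). The other lists gave adjusted p of 0.45 for tubulin genes (6 of 8 higher), 0.627 for pro-inflammatory macrophage genes (4 of 10, median -0.15 with a higher test direction), 0.156 for interferon gamma response (11 of 24, median -0.01 with a higher test direction), 0.48 for regulatory T cell genes (3 of 10, median -0.02 with a higher test direction) and 0.318 for cell cycle (14 of 22). They gave 0.744 for p53 targets (11 of 25, median -0.04 with a higher test direction), 0.257 for hypoxia (9 of 15), 0.188 for the unfolded protein response (10 of 17), 0.71 for heat shock (9 of 22, median -0.07 with a higher test direction) and 0.0997 for vascular genes (2 of 5). Adjusted over the list alone, 0 genes passed in any list without the block. With the block, counts adjusted over the list alone were 5 for cytotoxicity, 5 for dendritic cell maturation, 4 for GEF-H1, RhoA and AP-1, 3 each for NF-kB and heat shock, 2 for regulatory T cell genes and 1 each in 6 further lists.

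**Figure D3:**
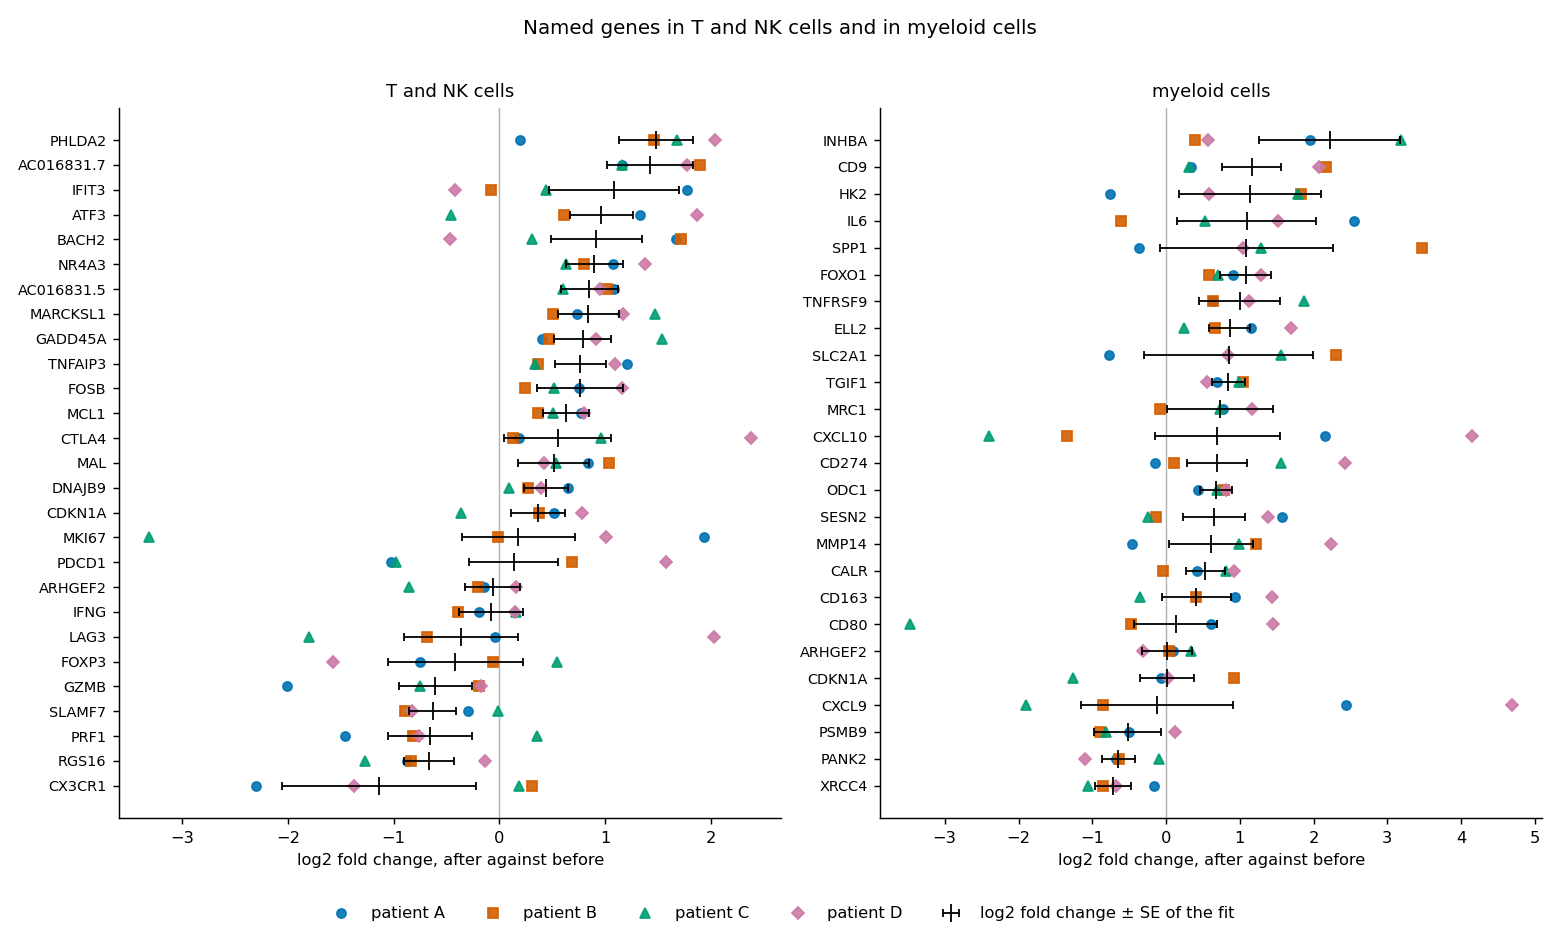
Log2 change after against before treatment, on the horizontal axis, of genes in T and NK cells and in myeloid cells, with a tick and bar for the fitted change and its SE and points for single patients A to D. NR4A3 and PHLDA2 lie above 0 in T and NK cells and TGIF1 in myeloid cells, each in 4 of 4 patients.

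In myeloid cells the comparison asked whether macrophages and monocytes shifted state. TGIF1, a transcription repressor of the TGF-beta pathway, had 56.9 ± 6.72 CPM before and 102 ± 22.0 after (SD, n = 4), a log2 change of 0.84 ± 0.22 (SE) in 4 of 4 patients. FOXO1, a transcription factor that insulin signals inhibit, had a log2 change of 1.08 ± 0.34, ELL2, an elongation factor, 0.86 ± 0.28, ODC1, the first enzyme of polyamine synthesis, 0.67 ± 0.22 and the membrane protein CD9 1.16 ± 0.40, all in 4 of 4 patients. INHBA, which encodes a subunit of activin A, had 39.5 ± 28.7 and 203 ± 303 CPM, a log2 change of 2.22 ± 0.96 in 4 of 4 patients, which was 0.34 without patient C after treatment. XRCC4, a DNA end-joining protein, at -0.72 ± 0.25 and PANK2, a coenzyme A enzyme, at -0.65 ± 0.23 were lower in 4 of 4.

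None of these genes passed in edgeR, where 0 of 8666 had an adjusted p under 0.05 without the patient block (108 unadjusted, 64 higher and 44 lower) and 0 with it (431 unadjusted). DESeq2 also gave 0, with 73 unadjusted. None of these unadjusted counts exceeded what chance alone would give. On simulated changes in myeloid cells, edgeR without the block called 8% of genes changed 2-fold and 80% of those changed 4-fold. In patients A, C and D the subset with most myeloid cells differed before and after treatment, so these sums mix a change inside cells with a change in subsets. In patient D FCN1 monocyte-like cells went from 52.1% to 31.9% and C1Q and CCL3 macrophage-like cells from 8.33% to 33.6%. In patient B C1Q and CCL3 macrophage-like cells led in both biopsies (67.3% and 68.8%). TGIF1 (ENSG00000177426) lies on chromosome 18 at 3411608 to 3459978, and INHBA (ENSG00000122641) on chromosome 7 at 41667168 to 41705834, where an antisense gene overlaps it.

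Unfolded protein response genes were higher as a set in myeloid cells, in 12 of 17 members with a median log2 change of 0.24 (limma's camera, adjusted p = 0.0035, 3 of 4 patients; adjusted p = 0.408 with an estimated correlation). Among them were CALR, a chaperone of the endoplasmic reticulum, at 0.53 ± 0.27 and SESN2, a stress gene, at 0.65 ± 0.42 (1.23 without patient B before). Activated fibroblast and collagen genes were higher in 6 of 6 measured members (median 0.44, adjusted p = 0.0392, and 0.0027 with the block, 4 of 4 patients; adjusted p = 0.618 with an estimated correlation), with INHBA and the matrix protease MMP14 (0.61 ± 0.57) among them. Scavenger macrophage genes were higher in 13 of 20 (median 0.22, adjusted p = 0.0719, and 0.019 with the block; adjusted p = 0.704 with an estimated correlation). Their members MRC1 (0.73 ± 0.72), a mannose receptor, and CD163 (0.41 ± 0.47), a haemoglobin scavenger receptor, were each higher in 3 of 4 patients. Hypoxia genes were higher in 15 of 18 (median 0.22, adjusted p = 0.0719, and 0.021 with the block; adjusted p = 0.699 with an estimated correlation), with the glycolytic enzyme HK2 at 1.14 ± 0.96 and the glucose transporter SLC2A1 at 0.85 ± 1.15. SPP1 itself had a log2 change of 1.09 ± 1.17 in 3 of 4 patients. Without patient C after treatment, SPP1 turned to -0.80, HK2 to -0.56 and SLC2A1 to -0.78, and without patient A after treatment MRC1 turned to -0.0046. MMP14 was 0.20 without patient C after, 0.30 without patient D before, 0.36 without patient B before and 0.97 without patient A before. CD163 was 0.10 without patient D before, 0.23 without patient A after and 0.73 without patient C before.

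The call of the unfolded protein list ended without patient D after treatment (adjusted p = 0.0917), and that of the collagen list ended in 6 of 8 omissions of 1 library, with the largest adjusted p of 0.893 without patient D before. Splits of the same 8 libraries into other groups of 4 gave 2 to 10 lists past the threshold in myeloid cells, against 2 here. The other lists in myeloid cells did not pass limma's camera. Adjusted p was 0.0796 for tubulin genes (7 of 9 higher), 0.45 for GEF-H1, RhoA and AP-1 (11 of 16), 0.222 for dendritic cell maturation (9 of 14), 0.594 for pro-inflammatory genes (8 of 19, median -0.12 with a higher test direction), 0.318 for type I interferon (14 of 25) and 0.776 for interferon gamma response (15 of 28). It was 0.257 for inhibitory receptors (3 of 6), 0.744 for naive T cell genes (4 of 8), 0.45 for cell cycle (6 of 10), 0.4 for p53 targets (13 of 24, median 0.03 with a lower test direction), 0.576 for NF-kB targets (10 of 19), 0.723 for heat shock (12 of 22, median 0.02 with a lower test direction), 0.869 for vascular genes (1 of 5) and 0.176 for mitochondrial transcripts (10 of 12). Adjusted over the list alone, 0 genes passed in any list without the block. With the block 1 gene passed in each of the inhibitory receptor and collagen lists. CD274, the checkpoint ligand PD-L1, had 12.7 ± 7.09 CPM before and 23.6 ± 7.89 after, a log2 change of 0.69 ± 0.40 in 3 of 4 patients. TNFRSF9, a costimulatory receptor, had 1.00 ± 0.55 in 4 of 4 patients (0.58 without patient C after). The chemokine genes CXCL9 (-0.13 ± 1.03) and CXCL10 (0.69 ± 0.85), which draw in T cells, were each higher in 2 of 4 patients, and the cytokine IL6 (1.09 ± 0.94) in 3 of 4. Without patient D after treatment CXCL9 was 0.07, CXCL10 -0.04 and IL6 -0.52, and CXCL9 was also 1.27 without patient B before and 0.19 without patient C after. The costimulatory ligand CD80 (0.13 ± 0.56), the immunoproteasome gene PSMB9 (-0.52 ± 0.46) and CDKN1A (0.01 ± 0.37) did not share a direction over the 4 patients. PSMB9 was -0.02 without patient B before and -0.30 without patient C after, and CD80 was -0.03 to -0.08 without 1 of patient B after, patient C before or patient D before.

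**Figure D4:**
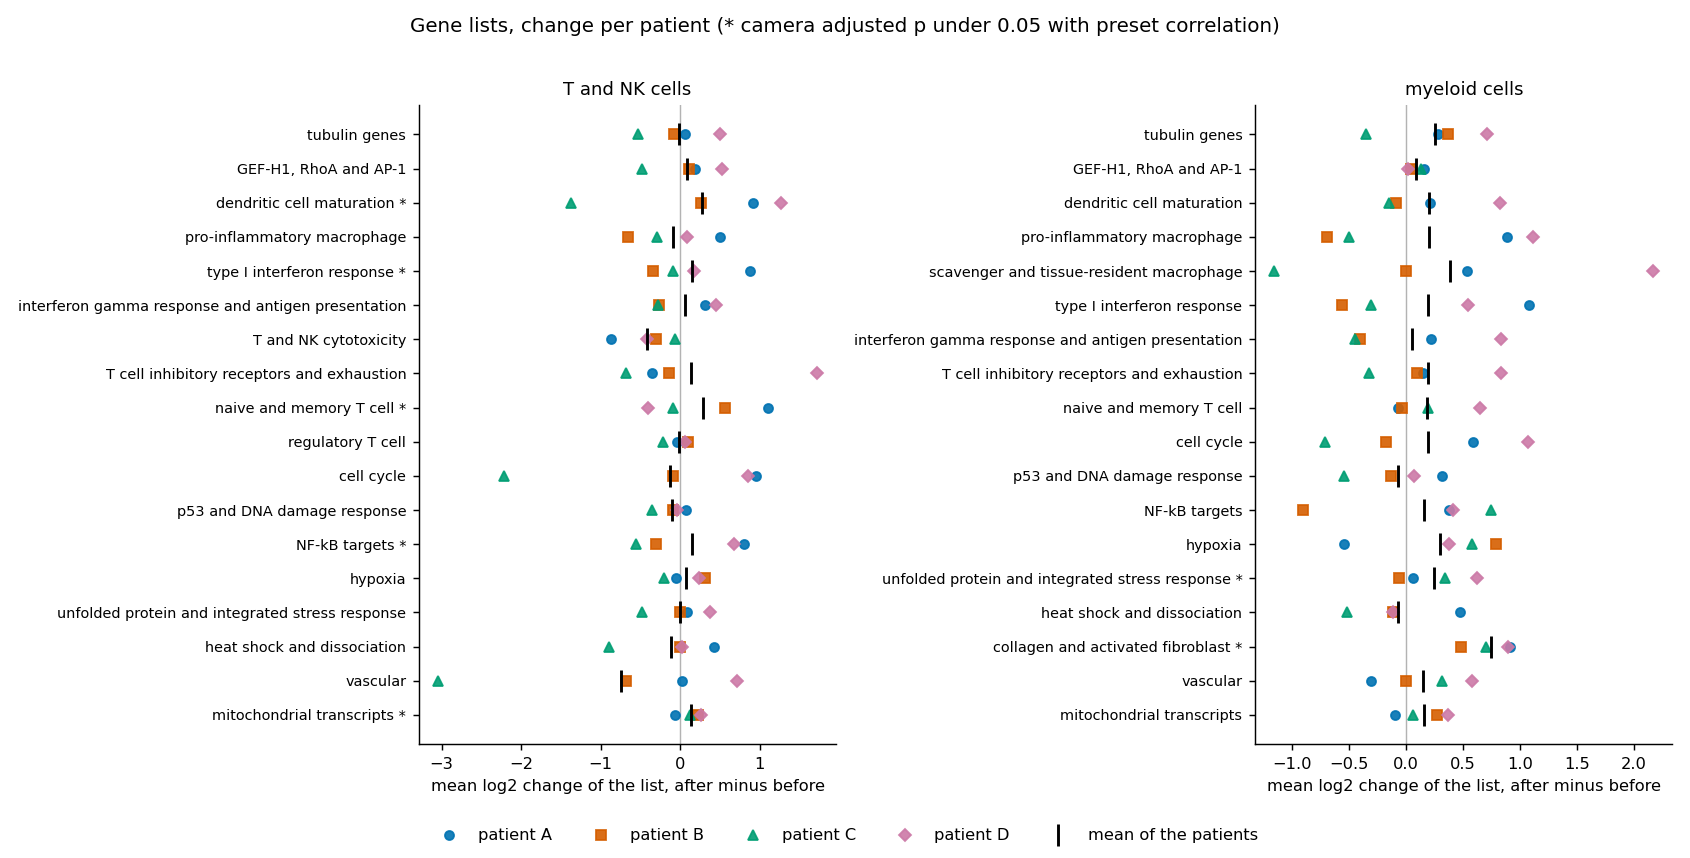
Mean log2 change of each gene list after against before treatment in T and NK cells and in myeloid cells, on the horizontal axis, with 1 point per patient A to D, a bar for their mean and a star for lists past limma's camera with the preset correlation. The cytotoxicity list in T and NK cells was below 0 and the collagen and activated fibroblast list in myeloid cells above 0 in each of the 4 patients.

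With all cells of a biopsy summed, the comparison described the whole tissue. MMP9, a matrix-degrading protease, had 16.8 ± 25.2 CPM before and 75.6 ± 108 after treatment (SD, n = 4) and was higher in 4 of 4 patients. It was the 1 gene to rise past the threshold when the patient was a block in edgeR (log2 change 2.28 ± 0.13, adjusted p = 0.0122), and without the block its log2 change was 2.17 ± 1.55, which was 0.35 without patient C after treatment and 4.13 without patient C before it. Each of these omissions kept patient C's other biopsy, unmatched, in a fit with no patient term. CXCL8, the neutrophil-attracting chemokine IL-8, had 67.1 ± 56.1 and 214 ± 107 CPM, a log2 change of 1.67 ± 0.60. PTGS2, the prostaglandin enzyme COX-2, had a log2 change of 1.08 ± 0.31, DLL4, a Notch ligand of new vessels, 1.83 ± 0.50 from 0.395 ± 0.122 CPM, and SERPINB9, the granzyme B inhibitor, 1.17 ± 0.43, each higher in 4 of 4 patients. CLDN5 (3.29 ± 1.16), a tight junction protein of endothelium, and CCL23 (1.95 ± 0.75), a myeloid chemokine near its detection limit, were also higher in 4 of 4. Without patient A after treatment CLDN5 was 1.92 and CCL23 1.22, and without patient B after treatment SERPINB9 was 0.62.

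Without the block, edgeR passed 0 of 18940 genes in summed cells (27 unadjusted, all higher), and DESeq2 passed 0 (55 unadjusted). Both unadjusted counts are under what chance alone would give. Without patient C, edgeR with the block passed 0 genes (1473 unadjusted), where MMP9 had a log2 change of 2.33 ± 0.18 (adjusted p = 0.171). On simulated changes in summed cells, edgeR without the block called 0% of the genes changed 2-fold or 4-fold and 38% of those changed 16-fold. MMP9 (ENSG00000100985) lies on chromosome 20 at 46008908 to 46016561, where SLC12A5-AS1 overlaps on the other strand. With the 6 patients sampled before treatment alone added to the group before treatment, 18 of the 23 genes followed in summed cells turned direction, among them CXCL8 (-0.12), PTGS2 (-0.60) and DLL4 (-1.24). MMP9 kept its direction there. CD274 had a log2 change of 0.93 ± 0.56 (4 of 4 patients) and the proliferation marker MKI67 -0.28 ± 0.47 (1 of 4). Of the list members, GADD45A had 0.83 ± 0.40 (4 of 4), TNFAIP3 0.87 ± 0.44 and the scavenger receptor MSR1 1.42 ± 0.96 (3 of 4). Without patient A after treatment MSR1 was 0.70, without patient D after TNFAIP3 was 0.55, and MKI67 ran from -0.73 (without patient D after) to -0.04 (without patient B after).

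Of 21 lists tested in summed cells, 14 passed limma's camera, 12 higher and 2 lower. Vascular genes were higher in 13 of 14 (median log2 change 1.35, adjusted p = 3.36e-11), scavenger macrophage genes in 19 of 20 (0.93, adjusted p = 3.36e-11) and interferon gamma response and antigen presentation genes in 28 of 28 (0.54, adjusted p = 1.88e-08). These list means were each higher in 3 of 4 patients, and the adjusted p was 0.408, 0.408 and 0.546 with an estimated correlation. NF-kB targets were higher in 15 of 19 (0.50, adjusted p = 3.86e-07, 4 of 4 patients), pro-inflammatory macrophage genes in 21 of 22 (0.55, adjusted p = 8.83e-06, 3 of 4), type I interferon genes in 23 of 25 (0.63, adjusted p = 3.32e-05, 3 of 4) and dendritic cell maturation genes in 13 of 17 (0.60, adjusted p = 0.000383, 3 of 4). With an estimated correlation the adjusted p was 0.408, 0.408, 0.618 and 0.408. Heat shock and dissociation genes (18 of 22, adjusted p = 0.0043) and inhibitory receptors (10 of 15, adjusted p = 0.0164, and 0.074 with the block) were also higher. So were the unfolded protein response (13 of 20, adjusted p = 0.0164) and GEF-H1, RhoA and AP-1 genes (14 of 18, adjusted p = 0.0185, 4 of 4 patients). Platelet genes were higher too (4 of 6, adjusted p = 0.0425, and 0.072 with the block). With an estimated correlation the adjusted p of these lists, in the order given from heat shock on, was 0.448, 0.636, 0.408, 0.627 and 0.408. Cytotoxicity genes were lower (9 of 16 members lower, median -0.06, adjusted p = 0.0031, lower in 2 of 4 patients), as were cell cycle genes (19 of 24, median -0.20, adjusted p = 0.0037, lower in 2 of 4), with adjusted p of 0.618 and 0.529 with an estimated correlation.

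Members with their log2 change in summed cells included HLA-DRA (1.25 ± 0.81), an antigen-presenting molecule, MRC1 (1.72 ± 1.10) and CD163 (1.10 ± 0.98) of scavenger macrophages, CDH5 (3.34 ± 1.75), the cadherin of endothelium, PRF1 (-0.55 ± 0.51) and the mitotic genes BIRC5 (-0.42 ± 0.35) and CCNB1 (-0.44 ± 0.34). Without patient A after treatment MRC1 was 0.30, CD163 0.66 and CDH5 1.34, and CD163 was also 1.97 without patient C before. Without patient B before treatment BIRC5 was -0.24 and CCNB1 -0.13, and BIRC5 was also -0.66 without patient C after. PRF1 was -0.31 without patient D before, -0.32 without patient C after and -0.95 without patient D after. The myeloid share of cells was also higher in 4 of 4 patients and the endothelial share was 3.76% in patient A after treatment. Patient C went against most higher lists, for example -1.20 for the mean change of the scavenger macrophage list against 1.96, 0.79 and 2.76 in patients A, B and D. Of the 14 lists the vascular list alone kept its call in every omission of 1 library (largest adjusted p = 0.0429, without patient A after), and leaving out patient B after treatment ended 10 calls, for example interferon gamma response (adjusted p = 0.0812) and pro-inflammatory genes (0.0767). Without patient D before treatment 6 calls ended, among them the scavenger macrophage list (adjusted p = 0.474), and without patient C after treatment the cytotoxicity list was higher instead (adjusted p = 0.0461). The lists that missed the threshold gave adjusted p of 0.776 for tubulin genes (4 of 11 higher, median -0.11 with a higher test direction), 0.181 for naive T cell genes (8 of 12), 0.4 for regulatory T cell genes (10 of 12), 0.525 for p53 targets (10 of 27, median -0.13 with a higher test direction), 0.491 for hypoxia (9 of 20), 0.0587 for collagen genes (21 of 22, median 0.56 with a lower test direction) and 0.625 for mitochondrial transcripts (3 of 12). Adjusted over the list alone, 0 genes passed in any list without the block. With the block 2 genes passed in each of the pro-inflammatory and NF-kB lists and 1 among p53 targets. HBB, a haemoglobin gene of red cells, had a log2 change of -5.11 ± 2.52, which was 1.42 without patient C before treatment, and COL1A1, a collagen gene, had 1.14 ± 1.74, which was -2.69 without patient A after treatment and -0.31 with the block.

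Epithelial cells were compared in patients A, B and D, the 3 with enough of them in both biopsies. HLA-DQA1, a class II antigen-presenting molecule, had 3.93 ± 2.12 CPM before and 34.2 ± 25.8 after (SD, n = 3), a log2 change of 3.12 ± 0.96 (SE), and HLA-DPA1 27.6 ± 29.3 and 141 ± 143 CPM (2.35 ± 1.19), both in 3 of 3 patients. GADD45A, a stress gene, had a log2 change of 0.97 ± 0.57, and CCN1, a secreted matrix protein, 1.17 ± 0.74, both in 3 of 3 patients. Without patient B after treatment CCN1 was 0.26, and without patient A before GADD45A was 0.63. HLA-DPA1 was 1.10 without patient D after and 3.73 without patient D before. Genes of phagocytes were counted in these cells as well, with CYBB, an oxidase subunit, at 0.311 ± 0.118 CPM before and 2.62 ± 3.21 after and C1QC at 1.08 ± 1.45 and 8.44 ± 11.2, far under the 1846 and 1990 CPM of C1QC in myeloid cells. Without patient A after treatment the log2 change of CYBB went from 3.05 to 1.28 and that of C1QC from 2.96 to 0.87. C1QC was 5.13 without patient B before. Reads of HLA genes depend on how each person's alleles match the reference, and reads of CCL3 can be shared with its copy CCL3L1, so these values are uncertain.

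Across the genes edgeR passed 0 of 17448 without the block (11 unadjusted, all higher) and 0 with it (517 unadjusted), and DESeq2 passed 0 (34 unadjusted). Each of these unadjusted counts is under what chance alone would give. On simulated changes in epithelial cells, edgeR without the block called 0% of the changed genes at each fold tried, up to 16. Other genes that differed most are not named, since genes of the tumour lineage of single patients were among them. In patient A 1 cluster held 62.6% of the epithelial cells before and 14.8% after treatment, so these sums mix clusters as well.

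Of 20 lists tested in epithelial cells 12 passed limma's camera, all higher. Interferon gamma response and antigen presentation genes were higher in 26 of 26 members (median log2 change 0.74, adjusted p = 6.99e-17, 2 of 3 patients), type I interferon genes in 23 of 25 (0.79, adjusted p = 4.62e-08, 2 of 3), scavenger macrophage genes in 11 of 13 (1.12, adjusted p = 2.1e-09, 2 of 3) and pro-inflammatory macrophage genes in 16 of 17 (0.76, adjusted p = 1.13e-05, 3 of 3). The adjusted p was 0.408 with an estimated correlation for each of these 4. Among the macrophage genes CCL2 (2.13 ± 1.00) and CCL3 (2.45 ± 1.18), both chemokines that attract leukocytes, had under 9 CPM after treatment. Without patient A after treatment they were 0.93 and 1.197. Heat shock and dissociation genes were higher in 21 of 22 (0.24, adjusted p = 0.000109, 3 of 3). The chaperone regulator BAG3 was at 0.86 ± 0.61 (0.21 without patient B after and 0.54 without patient A before). An effect of dissociation was not tested. Platelet genes were higher in 5 of 6 (0.69, adjusted p = 1.18e-06, 3 of 3). Both lists had an adjusted p of 0.35 with an estimated correlation. Dendritic cell maturation (7 of 11, adjusted p = 0.0031), GEF-H1, RhoA and AP-1 (14 of 18, adjusted p = 0.0073), NF-kB targets (14 of 19, adjusted p = 0.0171) and inhibitory receptors (7 of 12, adjusted p = 0.0322) were higher in 3 of 3 patients. Vascular genes (7 of 8, adjusted p = 0.0322, and 0.072 with the block) and collagen genes (13 of 17, adjusted p = 0.0392) were higher in 2 of 3. With an estimated correlation these 6 lists had adjusted p of 0.544, 0.408, 0.636, 0.408, 0.618 and 0.704.

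Interferon gamma response (largest adjusted p = 0.0429, without patient D after) and platelet genes (0.0282, without patient B after) kept their call in every omission of 1 library. Without patient A after treatment 8 of the 12 calls ended, such as type I interferon (adjusted p = 0.82), and the collagen list was lower instead (adjusted p = 4.32e-06). Hypoxia genes were lower in 16 of 20 (median -0.14, adjusted p = 0.062, and 0.021 with the block; adjusted p = 0.636 with an estimated correlation), with the prolyl hydroxylases P4HA1 (-0.46 ± 0.56) and EGLN3 (-0.47 ± 1.29) lower in 3 of 3 patients. P4HA1 ran from -0.93 (without patient D after) to -0.06 (without patient D before), and EGLN3 was 0.06 without patient A after and 0.41 without patient B before. The remaining lists gave adjusted p of 0.627 for tubulin genes (3 of 11 higher, median -0.08 with a higher test direction), 0.062 for cytotoxicity (6 of 13), 0.723 for naive T cell genes (4 of 10, median -0.13 with a higher test direction), 0.174 for cell cycle (6 of 24), 0.221 for p53 targets (11 of 27, median -0.03 with a higher test direction), 0.0796 for the unfolded protein response (13 of 20) and 0.744 for mitochondrial transcripts (8 of 12). Adjusted over the list alone, 0 genes passed in any list without the block. With the block 1 gene passed in each of the GEF-H1, RhoA and AP-1, dendritic cell maturation and p53 lists. When the patients sampled before treatment alone were added, 10 of the 16 genes followed in epithelial cells turned direction, HLA-DQA1 (-0.42) and HLA-DPA1 (-0.21) among them. CXCL8 had a log2 change of 1.66 ± 2.06 in 3 of 3 patients and -0.46 without patient D after treatment, CDKN1A 0.15 ± 0.55 (-0.25 without patient A after, -0.06 without patient B before and -0.02 without patient D before), and MKI67 -0.04 ± 0.58 (0.31 without patient B after and 0.30 without patient D before).

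**Figure D5:**
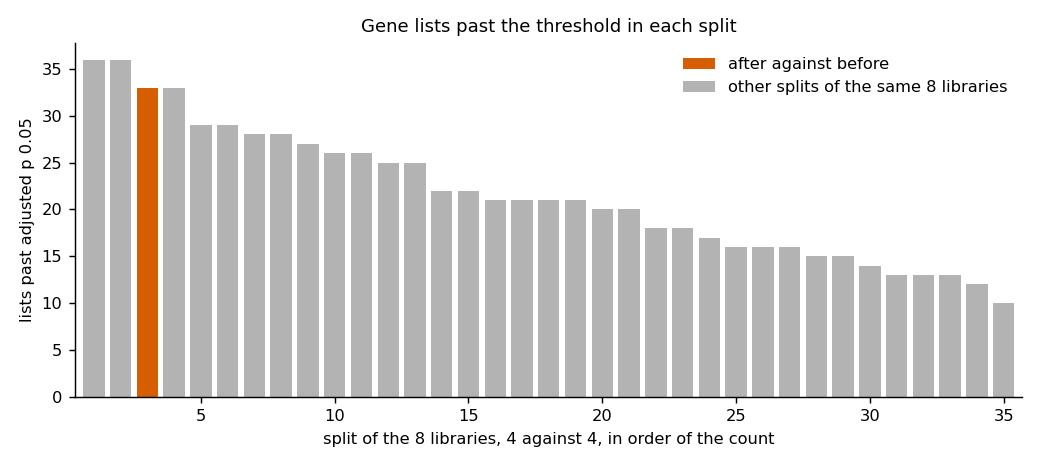
Number of gene lists past limma's camera over the 4 cell classes, on the vertical axis, for each of the 35 splits of the 8 libraries into groups of 4, ordered by that number on the horizontal axis. The coloured bar is after against before treatment with 33 lists, and the highest of the other splits had 36.

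Plinabulin's effects have been tied to ARHGEF2, which encodes GEF-H1, an activator of RhoA that microtubules hold until they come apart. ARHGEF2 (ENSG00000116584) lies on chromosome 1 at 155946851 to 156007070 and overlaps genes on the other strand. It had 49.97 ± 15.2 CPM before and 52.5 ± 20.9 after treatment in myeloid cells (SD, n = 4), a log2 change of 0.01 ± 0.34 (SE). In T and NK cells it had 22.2 ± 2.44 and 19.0 ± 6.40 CPM (-0.06 ± 0.26), and in summed cells 17.5 ± 8.73 and 18.0 ± 4.76 CPM (0.05 ± 0.41). Leaving out 1 library gave -0.19 to 0.19 in myeloid cells, -0.24 to 0.07 in T and NK cells and -0.14 to 0.44 in summed cells. In epithelial cells of patients A, B and D the log2 change was -0.14, with -0.54 to 0.48 on leaving out 1 library.

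Across the 10 biopsies before treatment, the level of ARHGEF2 in myeloid cells was set against 4 gene lists, each correlation with a permutation test. For pro-inflammatory macrophage genes Pearson's r was 0.45 (permutation p = 0.194) and Spearman's rho 0.36 (permutation p = 0.312). Dendritic cell maturation genes gave r = 0.38 (permutation p = 0.273) and rho = 0.45 (permutation p = 0.191). Interferon gamma response genes gave r = 0.27 (permutation p = 0.465) and rho = 0.24 (permutation p = 0.515). The other GEF-H1, RhoA and AP-1 genes gave r = -0.21 (permutation p = 0.573) and rho = -0.28 (permutation p = 0.429). The smallest adjusted p over the 4 relations was 0.545 for r and 0.515 for rho by permutation. Without the 2 libraries farthest from the median ARHGEF2 level, r was 0.50, 0.30, 0.45 and -0.13 in the same order. The libraries held 13 to 710 UMIs of ARHGEF2 in myeloid cells. In summed cells r was 0.50 (permutation p = 0.139), 0.52 (permutation p = 0.121), 0.64 (permutation p = 0.0535) and 0.40 (permutation p = 0.2498) in that order. The smallest adjusted p by permutation was then 0.185.

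Changed genes were not tested in fibroblasts, endothelial cells or B and plasma cells of the 4 patients, because 1, 0 and 2 patients had at least 20 such cells in both biopsies. For B and plasma cells, edgeR compared 7 libraries before with 2 after treatment and passed 0 of 7027 genes (494 unadjusted).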

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

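The comparisons of the true grouping with other splits of the libraries, and the test of MMP9 within myeloid cells, were chosen after their result was seen, and the other tests here before. Values per library, shares of cells among them, were examined in 46 groups of samples for 1 library far from the rest. Such a library was found in 9 groups. The nominal rate of 1 in 20, or about 2.3 groups, assumes normally distributed values. Shares are bounded and can be skewed, so whether 9 groups exceed chance cannot be told.

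Among the biopsies before treatment, B cells made up 30.2% of cells in patient J, against 11.96% in the next library. Plasmacytoid dendritic cells, which make type I interferon, made up 6.06% in the same patient, against 0.571%. Endothelial cells made up 8.88% in patient I, against 2.41%. Fibroblasts made up 21.1% in patient F, against 10.7%. Plasma cells made up 20.3% in patient E, against 7.55%. Among the biopsies after treatment, B cells made up 1.51% in patient B, against 0.083%. In patient A after treatment fibroblasts made up 15.3%, against 1.29%, and endothelial cells 3.76%, against 0.503%. CD8 T-like cells made up 25.8% of the T and NK cells of patient C after treatment, against 54.9% in the nearest library, in a library with 31 such cells. Of 31 genes followed in both T and NK and myeloid cells, 0 moved in opposite directions in every patient.

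Genes of scavenger macrophages were higher in summed cells after treatment, with a mean change of 1.06 ± 0.89 (log2, SE, n = 4). Myeloid cells carried part of it, since the mean change was 0.58 ± 1.00 with them taken out, a drop of 0.48 ± 0.15 that was seen in 4 of 4 patients. Whether a larger share of myeloid cells could account for most of it stays open, as the change left without them ran from -2.10 to 2.25 over the patients. Without patient D, who had the largest change, the mean was 0.48. That a few libraries set the mean stays open too, because patient C moved the other way (-1.28). RNA from other cells in the droplets also stays open, and a response to treatment is possible and untested without untreated repeat biopsies.

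Cytotoxicity genes were lower in T and NK cells after treatment in 4 of 4 patients, with a mean change of -0.43 ± 0.14 (log2, SE). After thinning each cell to 1000 UMIs the mean was -0.46 ± 0.08. This cannot decide whether a difference in depth contributed, since the sums were already scaled to CPM. Thinning also keeps the expected proportions of genes within each cell. Fewer killer cells among the T and NK cells stay open, since within CD8 T-like cells of 3 patients the mean was -0.38 ± 0.16, too wide to tell how much of the drop was left. These CD8 T-like cells mixed clusters themselves, as 1 cluster led by FGFBP2 and GNLY held 66 of 100 in patient D before and 78 of 285 after treatment, and 31 of 182 and 22 of 559 in patient A. Patient C had 21 cells deep enough to thin after treatment.

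MMP9 was higher in summed cells of 4 of 4 patients. A larger myeloid share is argued against as the whole cause, as MMP9 within myeloid cells had a log2 change of 1.78 ± 0.24 (edgeR with the patient as a block, adjusted p = 0.222). More SPP1 and C1Q macrophage-like cells are argued against as the whole cause in patients A and B alone, the 2 with enough cells. Within C1Q and CCL3 macrophage-like cells their mean change was 2.74 ± 1.32 (4.05 and 1.42). Patient A had 5 MMP9 UMIs in 23 such cells before treatment. Patient C, without whose biopsy after treatment the change in summed cells was 0.35, had too few such cells, so this explanation stays open there. The fit behind that value had no patient term and kept patient C's biopsy before treatment. A change within macrophages may therefore contribute, as a hypothesis drawn from these same data, and no other tissue response was tested.

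Without the patient block 0 genes passed for after against before in edgeR (27 unadjusted in summed, 110 in T and NK and 108 in myeloid cells) and DESeq2 (55, 51 and 73), and every split of the libraries has at least 0, so counts of 35 of 35 splits in summed, T and NK and myeloid cells say nothing about chance. The highest other split had 1795 genes in summed, 25 in T and NK and 7 in myeloid cells. In summed cells the 3 splits that kept both biopsies of every patient on 1 side gave 281, 1097 and 1795 genes, so the patients themselves structure these samples. Epithelial cells gave 10 of 10 splits with 0 genes (highest other 0), too few splits for a share under 0.05. With the patient block the splits that part every pair are also too few, at 1 of 8 in summed cells (1 gene, highest other 0), 3 of 8 in T and NK cells (4 genes, highest other 10), 8 of 8 in myeloid cells (0 genes, highest other 2) and 4 of 4 in epithelial cells (0 genes, highest other 0). For gene lists, 4 of 35 splits gave at least the 33 lists past the threshold (highest other 36), so chance cannot be excluded for that count. Of the 8 splits that part every pair, 3 gave as many lists, the true grouping included. Within T and NK cells the true grouping gave 5 lists and other splits up to 9. Within myeloid cells it gave 2 and other splits 2 to 10. These counts did not stand out from those of other splits either.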

How the results depend on the processing

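Leaving out patient C, counting the keratin-led cluster as epithelial and taking the FOXP3 cluster at Leiden resolution 2 as regulatory T cells were chosen after the results had been seen. Directions of the named genes held under most alternatives, with 97 of 1478 comparisons turning, and 26 of 296 did so for shares of cells. Of 91 named genes by class, 26 turned direction in some omission of 1 library, and 35 more kept it with a change moved by over 1.5 times. Each omission left that patient's other biopsy unmatched, so these counts also hold differences between patients. At the depth of these libraries edgeR called 24% of simulated 2-fold changes in T and NK cells, 8% in myeloid cells and 0% in summed and epithelial cells without the patient block, and 60%, 54%, 38% and 24% with it, and other depths were not tried. The difference in log2 odds was -0.30 for epithelial cells with the keratin-led cluster and 0.32 for the FOXP3 cluster. Where a result turned below the cause was not tested.

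The count of changed genes stayed at 0 under DESeq2 size factors, library totals without TMM, all 14 libraries, no doublet removal, the strict cell filter, each omission of 1 library and without patient C, and with the keratin-led cluster counted as epithelial. With the patient as a replicate block edgeR gave 1 gene in summed cells and 4 in T and NK cells, and without a filter on low counts 6 in T and NK cells (5 higher, 1 lower). The block left the count at 0 in myeloid and epithelial cells. Beside NR4A3, PHLDA2, AC016831.7, AC016831.5 and MMP9 it changed no call of a named gene. Without patient C the block gave 0 in all 3 classes that patient enters, with log2 changes that stayed as large from fewer samples (NR4A3 1.09, PHLDA2 1.34, AC016831.7 1.67, AC016831.5 1.04 and MMP9 2.33).

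The 33 lists past the threshold were 35 with library totals, 35 with the strict filter, 33 without doublet removal, 38 without patient C and 35 with the patient as a block, of which 30 were shared. The block ended the calls of inhibitory receptors and platelet genes in summed cells and of vascular genes in epithelial cells, and added cytotoxicity and the GEF-H1 list in T and NK cells, scavenger macrophage and hypoxia genes in myeloid cells and hypoxia genes in epithelial cells. Camera with an estimated correlation gave 0 lists and fry 0, also with the block. With all 14 libraries 16 lists passed (11 higher, 5 lower), 8 of them shared. Leaving out 1 library gave 20 to 48 lists, with 20 without patient B after, 21 without patient D before and 48 without patient C after. Of the 33 lists 3 kept their call in every such omission, 18 lost it in 1 to 3 omissions and 12 in 4 to 6.

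Adding the 6 patients with a biopsy before treatment alone (all 14 libraries) turned the most directions, and this grouping compares different people. Log2 odds of shares were then -0.84 for endothelial, 1.66 for epithelial, 0.46 for plasma and -0.0054 for plasmacytoid dendritic cells and 0.11 for C1Q and CCL3 macrophage-like cells. Log2 changes in summed cells were CXCL8 -0.12, PTGS2 -0.60, DLL4 -1.24, CLDN5 -0.17, SERPINB9 -0.52, CCL23 -2.80, HLA-DRA -0.20, HLA-DPA1 -0.17, MRC1 -0.66, CD163 -0.90, CDH5 -1.19, BIRC5 0.37, CCNB1 0.12, MKI67 0.44, TNFAIP3 -0.24, CD274 -0.37, COL1A1 -0.93 and ARHGEF2 -0.42. In epithelial cells they were HLA-DQA1 -0.42, HLA-DPA1 -0.21, CYBB -1.81, C1QC -2.02, C1QB -1.30, CCL2 -2.23, CCL3 -0.57, EGLN3 0.35, MKI67 0.70 and ARHGEF2 0.17. FOXP3 was 0.63 in T and NK cells, and in myeloid cells CD163 was -0.13, CXCL9 0.61, ARHGEF2 -0.07 and CDKN1A -0.10. Lists that turned had adjusted p in limma's camera of 0.0307 for type I interferon, 0.262 for interferon gamma response, 1.61e-10 for cell cycle (now higher), 0.873 for the unfolded protein response and 0.149 for vascular genes in summed cells. In epithelial cells these were 0.883 for pro-inflammatory and 0.438 for scavenger macrophage genes, 0.617 for type I interferon, 0.535 for inhibitory receptors, 0.137 for collagen and 0.883 for vascular genes.

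Other settings turned few values. The strict filter gave log2 odds of -0.031 for mast cells and log2 changes of 0.0088 for ARHGEF2 in T and NK cells, -0.0032 for CDKN1A in myeloid and 0.015 for MKI67 in epithelial cells. Leiden resolution 0.5 gave 0.99 for fibroblasts. The class there held clusters of 587 and 29 cells, with 99.7% and 93.1% from 1 library. It lacked the fibroblast cluster of 1748 cells found at resolution 1, so this value describes a smaller class. Shares among immune cells alone gave -0.029 for mast cells. Library totals without TMM gave ARHGEF2 -0.014 and CDKN1A -0.077 in myeloid and MKI67 0.063 in epithelial cells, and no doublet removal CDKN1A -0.049. The patient block in edgeR gave LAG3 0.091 in T and NK cells, CXCL9 0.78 and CDKN1A -0.049 in myeloid cells and COL1A1 -0.31 in summed cells. Without patient C CXCL9 was 0.12 and ARHGEF2 -0.075 in myeloid cells, ARHGEF2 -0.0077 in summed cells, and the cytotoxicity list in summed cells turned with an adjusted p of 0.24 in limma's camera. With the block as well, LAG3 was 0.31, CXCL9 1.81 and ARHGEF2 -0.042. The correlation of ARHGEF2 with GEF-H1, RhoA and AP-1 genes was 0.40 in summed cells.

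Leaving out 1 library at a time gave ranges that cross 0. For log2 odds of shares these were -2.03 to 1.06 for plasma, -0.64 to 1.48 for mast, -0.34 to 1.82 for endothelial, -1.27 to 0.13 for T and NK and -2.76 to 0.13 for epithelial cells. For subsets they were -0.54 to 0.44 for cycling, -1.11 to 0.73 for NK-like, -0.26 to 0.95 for regulatory T-like and -1.45 to 0.42 for C1Q and CCL3 macrophage-like cells. In T and NK cells log2 changes ran from -2.99 to 0.60 for CX3CR1, -0.24 to 0.066 for ARHGEF2, -0.28 to 0.41 for PDCD1, -0.71 to 0.15 for LAG3, -0.24 to 0.16 for IFNG, -1.14 to 0.082 for FOXP3, -0.40 to 0.63 for MKI67 and -0.34 to 1.498 for IFIT3. In myeloid cells they ran from -0.80 to 2.39 for SPP1, -0.0046 to 1.36 for MRC1, -0.52 to 1.51 for IL6, -0.54 to 1.27 for CXCL9, -0.041 to 1.65 for CXCL10, -0.56 to 1.99 for HK2, -0.78 to 2.43 for SLC2A1, -0.19 to 0.19 for ARHGEF2, -0.078 to 0.87 for CD80 and -0.26 to 0.22 for CDKN1A. In summed cells COL1A1 ran from -2.69 to 3.13, HBB from -5.78 to 1.42 and ARHGEF2 from -0.14 to 0.44. In epithelial cells CXCL8 ran from -0.46 to 5.99, EGLN3 from -1.39 to 0.41, CDKN1A from -0.25 to 0.68, MKI67 from -0.52 to 0.31 and ARHGEF2 from -0.54 to 0.48. Adjusted p of lists that turned ran in epithelial cells from 0.000169 to 0.722 for NF-kB targets, 4.32e-06 to 0.977 for collagen, 1.31e-09 to 0.82 for type I interferon, 0.0011 to 0.755 for inhibitory receptors and 0.0025 to 0.616 for vascular genes. In summed cells they ran from 0.000208 to 0.979 for the GEF-H1 list, 1.47e-05 to 0.944 for inhibitory receptors, 6.92e-13 to 0.643 for type I interferon and 1.01e-05 to 0.523 for cytotoxicity, all in limma's camera.

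Changed genes in fibroblasts and endothelial cells, and in B and plasma cells of the 4 patients, were not run for lack of cells, nor was the epithelial test without patient C, who does not enter it.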

Other observations

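All values here were chosen after the data were seen and have no test of their own. Complement transcripts of macrophages were also counted in cells of the epithelial class. Whether they came from other cells was not tested. C1QB, a macrophage complement gene, had 2.93 CPM before and 18.0 CPM after treatment in epithelial cells of patients A, B and D, and 3628 and 3497 CPM in myeloid cells of patients A to D. C1QC had 1.08 and 8.44 CPM in epithelial cells. Their log2 changes in epithelial cells, 2.61 for C1QB and 2.96 for C1QC, were 0.55 and 0.87 without patient A after treatment and 5.08 and 5.13 without patient B before.

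Between 2 macrophage-like clusters, most MMP9 UMIs lay in C1Q and CCL3 macrophage-like cells in 6 of 8 libraries. In patient C after treatment 334 lay there and 1257 in SPP1 and C1Q macrophage-like cells, and in patient D before 1 lay in each. In C1Q and CCL3 macrophage-like cells MMP9 had 9.51, 96.4, 1204 and 22.7 CPM before and 160, 270, 3222 and 48.5 CPM after treatment in patients A, B, C and D. The libraries with fewest such cells were patient D before, with 4 cells, and patient C after, with 9. In SPP1 and C1Q macrophage-like cells MMP9 had 1171 CPM before and 5910 after treatment in patient C, and in patient B 7 UMIs before and 1 after.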
